A study of Mus musculus with 6 samples.

How the data were processed

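Total RNA from the brains of 6 female littermate mice aged 123 days was hybridised to the Affymetrix Mouse Genome 430 2.0 array, 1 array per mouse, per the labels. The labels placed 4 mice in the melanotransferrin knockout group and 2 in the wild-type group, and gave no batch, scan date or pairing. Each mouse was a separate animal, so p-values measured the spread between mice together with that between arrays. The groups were taken from the labels alone, and the numbers 1 to 4 and 1 to 2 used below followed the order of deposit and only name an array.

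The deposited table held 1 signal intensity per probe set and array on a linear scale. A probe set is a group of short probes that together measure a transcript. GCOS 1.3, the Affymetrix operating software, is the only tool named, per the submitters' processing notes. The summary method, the detection calls, the scaling target and any filter are not given in the sources used here. The mean of the middle 96% of the deposited intensity values was 1000.0 on every array, so the authors' values had been scaled to a common level. No log, centring or ratio had been applied, and all values were above 0. The number of arrays limits the precision, and with 4 against 2 arrays an exact permutation test over the 15 possible splits cannot give a p below 0.0667.

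The table listed 45101 probe sets, of which 64 were Affymetrix controls and were left out. Gene symbols came from the platform annotation given with the table and were set against the gene table of assembly GRCm38.p6 by gene identifier, which changed 0 symbols. Of the 45037 remaining probe sets, 34945 had 1 gene symbol, 932 had several and 9160 had none, and no gene was named from a probe set with several symbols. Where a gene had several probe sets, they are told apart below by brightness or by p. The assembly was used only for names and for the order of genes along chromosomes, since the series names no genome build.

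Signals were taken to the log2 scale after adding 49.6, the 20th percentile of the table, so that fold changes of dim genes are understated. The 40% of probe sets with the lowest mean log2 value, a mean signal on that scale of up to 142.811, were left out, which kept 27022 probe sets. Of these, 23062 had 1 symbol and stood for 13300 genes. The contrast was knockout minus wild type, with no covariate, fitted by lmFit and eBayes with an intensity trend in limma 3.58.1 under R 4.3.3. The fit had 4 residual degrees of freedom and a prior of 6.77. P-values were 2-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05 on the adjusted value. Group values are given as mean signal ± SD over the mice, and standard errors belong to the log2 fold change. A 2-sided exact permutation test of the melanotransferrin probe set and 95% confidence intervals were computed on the same values. Plots were drawn in Python 3.11.15.

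Gene lists were tested with camera from limma, with a correlation of 0.01 between genes and 1 probe set per gene, the one with the highest mean. Adjustment was over the 23 lists. The lists were iron uptake, storage and export; heme and iron-sulfur clusters; transport of other metals; the oxidative stress response; and the plasminogen system. Cell type lists covered neurons, astrocytes, oligodendrocytes, microglia and immune cells, endothelium and pericytes, choroid plexus and ependyma, meninges and vascular smooth muscle, and blood. Region lists covered the pituitary, cerebellum, striatum, hippocampus and cortex, and hypothalamus and midbrain. State lists covered immediate early genes, clock and glucocorticoid genes, the interferon response, heat shock and endoplasmic reticulum stress, and myelin lipid and cholesterol genes. Camera with an estimated correlation, camera on ranks, and fry, which tests a list without setting it against other genes, served as alternatives. A list level on an array is the mean log2 value of its members, relative to each gene's mean over the 6 arrays and to all tested genes on that array. The neighbours of the melanotransferrin gene were the 100 annotated genes on each side of it on chromosome 16.

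Genes were named by a fixed rule. It took the melanotransferrin probe set, and in each direction the called genes with the largest fold change and no overlap between the groups. Where fewer than 3 genes were called, it took the 10 genes with the smallest p in that direction and no overlap, as values that did not pass. It added list members past 0.05 when adjusted over the list alone, and, for lists past the camera threshold with no such member, the 2 with the smallest p. It also took Tfrc, Trf, Fth1, Ftl1, Slc40a1, Slc11a2, Aco1, Ireb2 and Apod where measured. Trf and Ftl1 lay only on probe sets with several symbols and are not reported. The groups, the test, the offset, the filter, the lists, this rule and the alternatives that follow, except those said to be added, were chosen before the data were examined.

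The alternatives were quantile normalisation, median centring, an offset 4 times larger or 0.25 times as large, no dim filter, a filter at the lowest 60%, eBayes without the trend, robust eBayes, array weights, and leaving out each array in turn. Leaving out knockout 2 and wild type 1 together was added after the data were seen, as were a window of 400 genes on each side, a test of the share of neighbours with an unadjusted p below 0.01, and a list of 14 further cerebellum genes, whose own values had not been looked at. A count of bright genes at least 4-fold lower on 1 array was added in the same way. The fit was tested on simulated data for knockout minus wild type with 27022 probe sets. It called 57 of 87 probe sets changed 2-fold (65.5%), 80 of 81 changed 4-fold (98.8%), and 10 unchanged ones. The simulated noise was normal and of equal spread on all arrays. These rates need not hold for the deposited data, where wild type 1 stood apart. In the same test on 13323 genes, a list shifted by 0.3 on the log2 scale reached an adjusted p of 4.52e-08, and 0 of the 21 other lists were called by camera. The simulated values were drawn independently for each gene. In the deposited data the estimated correlation was 0.553 for the cerebellum list, 0.197 for endothelium, 0.152 for interferon and 0.0899 for the clock list. The lack of false list calls in the simulation therefore does not carry over to such lists.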

Results

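Brain RNA was profiled in 4 mice lacking melanotransferrin and in 2 wild-type mice of the same litter, all females of 123 days. The strain is given as C57BL/6 for the wild type and as C57BL/6 - Lucy for the knockout, where the last word is not explained in the sources used here. Melanotransferrin, encoded by Meltf, is an iron-binding membrane protein of the transferrin family. The design holds a single comparison, knockout against wild type, which asks which transcripts of the brain differ when melanotransferrin is missing. Median signals were 267.9, 238.2, 248 and 278.3 in knockouts 1 to 4 and 192.5 and 240.3 in wild types 1 and 2, with the trimmed mean equal on all arrays. Correlations between pairs of arrays over the tested probe sets ran from 0.949 to 0.976, and no pair was identical.

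Array wild type 1 stood apart from the rest. It had 24.5% of its probe sets below the added offset, against 17.6% to 20.2% on the other arrays, and its mean correlation with them was 0.956 against 0.961 to 0.970. Its bioB and cre hybridisation controls read 862.9 and 54103, against ranges of 1162 to 1717 and 80094 to 103463 elsewhere. The 3′ to 5′ ratio of Gapdh was 1.05 on it and 0.826 to 0.909 on the others, while that of actin, 2.35, lay within the range of the others, 1.83 to 2.75. The first principal component, 34.0% of the variance, separated this array from the other 5. Xist, the RNA of the inactive X chromosome, was at least 4527 on 1 of its probe sets in every mouse, and no Y-linked probe set of Uty, Kdm5d or Eif2s3y exceeded 126.8, which matched the sex on the labels.

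Meltf itself was dim and did not separate the groups. Its only probe set had a signal of 113 ± 37.0 (SD, n = 4) in the knockout and 188 ± 58.1 (SD, n = 2) in wild type. The knockout mice read 80.7, 132.9, 155.9 and 84.1, and the wild-type mice 146.5 and 228.7, so that the groups overlapped. The log2 fold change was -0.55 with a standard error of 0.38 and a 95% confidence interval from -1.38 to 0.29 (exact permutation p = 0.2, limma adjusted p = 0.784), and it was -0.29 without wild type 2. The mean level lay at the 38.2 percentile of all probe sets, below the dim filter, and this estimate came from the fit without that filter. The position of the probes relative to the deleted part of the gene is not given in the sources used here, so the value does not check the labels.

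**Figure D1:**
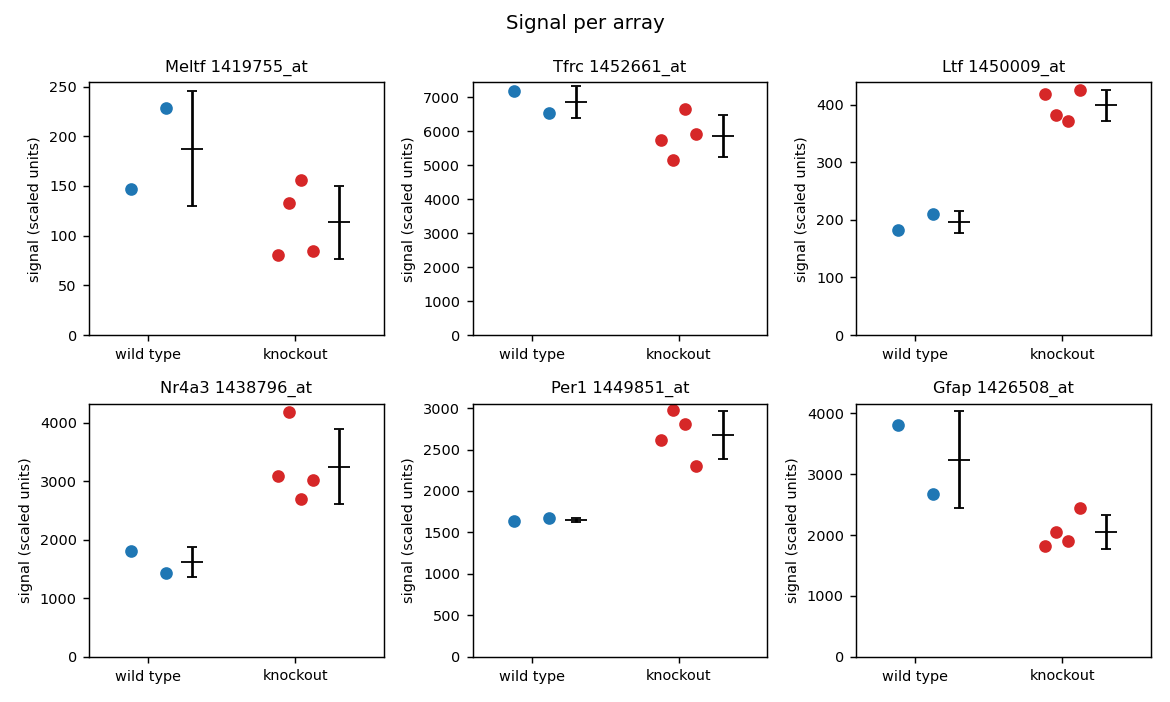
Signal in scaled units on each array, wild type in blue and knockout in red, for Meltf, Tfrc, Ltf, Nr4a3, Per1 and Gfap, with bars for the mean ± SD of 2 and 4 mice. The groups overlap for Meltf and Tfrc, while the 4 knockout mice lie above both wild-type mice for Ltf, Nr4a3 and Per1 and below them for Gfap.

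The lowest p-values among transcripts that were lower in the knockout belonged to Pcnp, Plcxd2, Bdh1 and Slc35a5, all 4 of them genes of chromosome 16, as Meltf is. Pcnp, which encodes a nuclear protein with PEST sequences, read 2652 ± 250.1 (SD, n = 4) in the knockout and 5756 ± 423 (SD, n = 2) in wild type on the dimmer of its 2 probe sets. This was 2.15-fold lower, with a log2 fold change of -1.11 and a standard error of 0.14. Plcxd2, a phospholipase C domain gene, was 1.97-fold lower, and Slc35a5, of the nucleotide sugar transporter family, 1.80-fold lower. Bdh1, the mitochondrial enzyme that interconverts ketone bodies, had a log2 fold change of -0.77. None of these passed the threshold in limma: the adjusted p was 0.245 for Pcnp, the smallest of the whole comparison, and 0.376 for the other 3.

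Other probe sets of these genes did not all differ by as much. The brighter Pcnp probe set read 13302 ± 304.7 (SD, n = 4) against 15047 ± 540 (SD, n = 2), a log2 fold change of -0.18 with a standard error of 0.13. For Plcxd2 the log2 fold change was -0.98 on the probe set with the smallest p and -0.37 on the other. Bdh1 was -0.77 on its brighter probe set and 0.13 on its dimmer one. Slc35a5 was -0.85 on its brightest probe set and -1.30 on another, but 0.094, 0.17 and 0.058 on the other 3. A similar split was seen for Apod, the lipid carrier apolipoprotein D, also of chromosome 16. Its bright probe set read 20613 ± 3921 (SD, n = 4) against 24173 ± 5107 (SD, n = 2), a log2 fold change of -0.23 with a limma adjusted p of 0.770, which was -0.45 without wild type 1 and -0.016 without wild type 2. A dim Apod probe set, left out by the filter, read 39.3 ± 37.1 (SD, n = 4) against 697.2 ± 118.4 (SD, n = 2). Its log2 fold change was -3.14 without the filter (limma adjusted p = 0.534), and with an offset 4 times larger, which let it pass the filter, it was -1.92 with an adjusted p of 0.0333. Its knockout mean lay below the usual offset, which therefore set the size of these values.

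Of the 27022 tested probe sets, 0 passed an adjusted p of 0.05 in limma, while 2108 had an unadjusted p below 0.05. An even spread of p-values would give 1351. Wrong groupings that put wild type 1 with knockout 4, 2 or 1 gave 2223, 2127 and 2122 in the same fit. All other wrong groupings gave 491 to 1374. The excess over 1351 therefore need not come from the genotype. Of these 2108, 1527 were higher and 581 lower in the knockout, and among the 412 with an unadjusted p below 0.01 the split was 348 to 64. The direction of this split depended on scaling: 72.4% of those below 0.05 were higher in the knockout with the deposited scaling, 60.2% after quantile normalisation and 17.6% after median centring. Median centring moved the median log2 fold change of all probe sets from 0.036 to -0.18. The knockout and wild-type values did not overlap for 4401 probe sets, or 16.3%, where chance gives 13.3%. The count depended on wild type 1: with that array as the only wild type, 414 probe sets passed, and with wild type 2 as the only one, 0 passed and 812 had an unadjusted p below 0.05.

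Among transcripts that were higher in the knockout, Olfr701, an olfactory receptor gene, read 297.1 ± 73.2 (SD, n = 4) against 25.8 ± 8.91 (SD, n = 2), a log2 fold change of 2.18 with a standard error of 0.33. Prkab2, a regulatory subunit of the energy sensor AMP-activated protein kinase, was 4.01-fold higher and Defa39, an alpha-defensin gene, 3.56-fold higher. Slitrk3, a synaptic adhesion protein, was 3.47-fold higher, Ndrg1 3.10-fold, Tgs1, which hypermethylates the caps of small nuclear RNAs, 2.85-fold, and Fank1 2.75-fold. The wild-type means of these 7 genes ran from 25.8 to 174.3. Those of Olfr701 and Prkab2, 25.8 and 32.4, lay below the added offset, so the offset set the size of both values, with log2 fold changes of 1.13 and 1.06 at an offset 4 times larger and 3.01 and 2.70 at 0.25 times as large. The log2 fold changes of Slitrk3, Defa39 and Tgs1, 1.79, 1.83 and 1.51, were 1.11, 1.18 and 1.002 at the larger offset. Xist was 1.98-fold higher on 1 probe set, but on another the knockout range of 10233 to 16572 overlapped the wild-type values of 6288 and 12960. The uncharacterised 2610507B11Rik and Gm19439 were 1.92-fold and 1.68-fold higher. For several of these genes other probe sets differed less or the other way: the brightest ones of Prkab2, Tgs1, Fank1, Ndrg1 and 2610507B11Rik had log2 fold changes of 0.099, -0.13, 0.042, -0.27 and -0.088, and 2 of the 5 tested Ndrg1 probe sets were higher. The limma adjusted p was 0.376 for each of these 10 genes, so none passed.

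Further lower transcripts included Gfap, the intermediate filament of astrocytes, whose probe set with the smallest p read 1482 ± 153.4 (SD, n = 4) against 2289 ± 296.6 (SD, n = 2), 1.53-fold lower. Its other 2 probe sets were lower as well, with log2 fold changes of -0.63 and -0.70. Btg2, an antiproliferative immediate early gene, had a log2 fold change of -0.68. Poglut2, a protein O-glucosyltransferase, was 1.88-fold lower, Ccdc126 1.80-fold, Tmem41b, a membrane protein of the endoplasmic reticulum, 1.68-fold and Mtfr1l, a mitochondrial fission regulator, 1.61-fold, with a log2 fold change of -0.69 that was -0.39 without wild type 1. Of the 6 tested probe sets of Tmem41b, 4 were lower and 2 were not, and 2 of the 3 of Mtfr1l were lower. The limma adjusted p for these 6 genes ranged from 0.434 to 0.599.

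No shift of the iron handling genes as a group was detected. Of the 44 genes on that list 34 were measured, 16 higher and 18 lower in the knockout, and 0 passed in limma over all genes or when adjusted over the list alone, with 5 at an unadjusted p below 0.05. The list's camera adjusted p was 0.928, with a median log2 fold change of -0.029 and a mean of 0.045, so the median and the mean differed in sign. Tfrc, the receptor for iron-loaded transferrin, read 5867 ± 625.1 (SD, n = 4) against 6871 ± 464.5 (SD, n = 2), a log2 fold change of -0.23 with a standard error of 0.14 (limma adjusted p = 0.688). The ferritin heavy chain gene Fth1 was 0.25 with a standard error of 0.21, the iron exporter Slc40a1 -0.15, the metal importer Slc11a2 -0.10, and the iron regulatory proteins Aco1 and Ireb2 -0.17 and -0.072. Fth1 was -0.080 without wild type 1, Slc11a2 was 0.073 without knockout 4, and Ireb2 was -0.14 without wild type 1 and -0.0048 without wild type 2. These values belong to the brightest probe set of each gene, and another was 0.40 for Slc11a2, with no overlap between the groups, and 0.030 for Aco1.

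The iron genes with the smallest p went both ways, and none passed. Tmprss6, a protease that restrains hepcidin, read 413.2 ± 145.8 (SD, n = 4) against 132.6 ± 9.90 (SD, n = 2). Ltf, which encodes the iron-binding lactotransferrin, read 399.2 ± 26.9 (SD, n = 4) against 196.1 ± 19.4 (SD, n = 2), 1.83-fold higher. Both had a limma adjusted p of 0.0554 when adjusted over the list alone and 0.599 over all genes. The ferric reductase Cybrd1 and the mitochondrial iron importer Slc25a37 had log2 fold changes of 0.83 and 0.41, while Ncoa4, the receptor that delivers ferritin for breakdown, and the ferroxidase Heph had -0.32 and -0.59. These 6 were listed for their p after the values were seen, and the balance of higher and lower among small p-values depended on scaling, as given above. Fry's test of whether members change in either direction gave an adjusted p of 0.00501 for this list. Fry's test of a common direction gave 0.887. The value for either direction was not recomputed with arrays left out or with other scaling. Fry does not set a list against other genes, and small p-values were in excess over the whole array. There, 2108 probe sets had an unadjusted p below 0.05 in limma, where an even spread of p-values would give 1351. By itself the fry value therefore cannot set the iron genes apart from other genes. For change in either direction, fry's adjusted p was below 0.05 for this list and the immediate early list only. Of the other lists, the clock and glucocorticoid list had the lowest, 0.117.

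The clock and glucocorticoid list lay higher in the knockout. Of its 22 measured genes 18 were higher, with a median log2 fold change of 0.13 (camera adjusted p = 0.0129, and adjusted p = 0.889 with an estimated correlation). Per1, a core clock gene, read 2675 ± 289.3 (SD, n = 4) against 1653 ± 24.5 (SD, n = 2), 1.59-fold higher, and was the 1 member to pass in limma when adjusted over the list alone (adjusted p = 0.0199), with 0.0620 without knockout 2, 0.0865 without knockout 3 and 0.0605 without wild type 1, where its log2 fold change was 0.62, 0.65 and 0.66 against 0.67 with all arrays. Over all genes 0 members passed in limma, and 5 had an unadjusted p below 0.05. The clock genes Npas2 and Ciart were 0.85 and 0.62 on the log2 scale, Sgk1, a kinase induced by glucocorticoids, 0.68 and Cdkn1a, a cell cycle inhibitor, 0.61. The list level was 0.21, 0.17, -0.11 and 0.015 in knockouts 1 to 4 and -0.050 and -0.24 in wild types 1 and 2. Without wild type 2 the camera adjusted p was 0.414.

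Immediate early genes, which neurons switch on within minutes of activity, went both ways. Of 20 measured, 14 were higher and 6 lower, the camera adjusted p was 0.0702 (0.889 with an estimated correlation), and fry gave an adjusted p of 0.0367 for change in either direction. The limits given above for fry's value on the iron list hold for this one too. When adjusted over the list alone, 3 members passed in limma and 0 passed over all genes, with 8 at an unadjusted p below 0.05. They were the nuclear receptor Nr4a3 at 3252 ± 642.7 (SD, n = 4) against 1622 ± 262.3 (SD, n = 2), 1.96-fold higher with a list-alone adjusted p of 0.00609, Per1 with 0.00906, and Btg2, which was lower, with 0.0117. Without wild type 2 none of the 3 passed, at 0.0508, 0.0508 and 0.136, with log2 fold changes of 0.81, 0.69 and -0.50 against 0.97, 0.67 and -0.68 with all arrays. Egr2 and Egr1 had log2 fold changes of 1.04 and 0.48, and Ier2 and Dusp1 -0.63 and -0.36. Knockout 2 had the highest list level, 0.31, and knockout 4 the lowest, -0.18.

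Astrocyte markers were lower in 9 of 14 cases, with a camera adjusted p of 0.124 for the list. The water channel Aqp4, at 5303 ± 836.4 (SD, n = 4) against 8302 ± 1721 (SD, n = 2), and the brightest Gfap probe set, at 2056 ± 278.1 (SD, n = 4) against 3242 ± 797.5 (SD, n = 2), passed in limma when adjusted over the list alone (adjusted p = 0.0351 for both) and not over all genes (adjusted p = 0.615 for both). The list level was highest in the dim array wild type 1, 0.15, and without that array the list-alone adjusted p of both was 0.570, with log2 fold changes of -0.43 for Aqp4 and -0.38 for Gfap against -0.64 and -0.63 with it. Both also missed that threshold without knockout 1, 2 or 3, with log2 fold changes of -0.70, -0.53 and -0.65 for Aqp4 and -0.58, -0.63 and -0.60 for Gfap. Endothelium and pericyte markers lay lower, 16 of 21, at a camera adjusted p of 0.0405, with 0.889 as the adjusted p for an estimated correlation. The junction genes Esam and Ocln had log2 fold changes of -0.50 and -0.70, and 0 of the 21 passed in limma, with 2 at an unadjusted p below 0.05. The interferon response list lay lower too, 16 of 20 genes (camera adjusted p = 0.0469, and adjusted p = 0.889 with an estimated correlation), with the antiviral genes Oas1a and Oasl2 at -0.66 and -0.61. None of its members passed in limma, and 1 had an unadjusted p below 0.05. Oas1a lay from -0.74 to -0.54 with any 1 array left out, and Esam was -0.61 without wild type 1. Wild type 1 held the highest level of the endothelium and interferon lists, 0.27 and 0.35, while the other 5 arrays lay from -0.14 to 0.044 and from -0.17 to 0.012. Without it the camera adjusted p was 0.630 and 0.966, the interferon list lay higher in the knockout, and Ocln and Oasl2 were -0.20 and -0.23.

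The cerebellum list was lower in the knockout, 13 of 15 genes, with a median log2 fold change of -0.45 (camera adjusted p = 0.0313, and adjusted p = 0.889 with an estimated correlation). Its values were set by 1 mouse. In knockout 2, Pcp2, a Purkinje cell gene, read 185.8 against 22260 to 34050 on the other 5 arrays, and Gabra6, a GABA receptor subunit of granule cells, read 87.6 against 6938 to 15711. The list level was -2.04 in that mouse and 0.062 to 0.56 in the others. Cbln1, a synaptic organiser released by granule cells, and Calb1, a calcium buffer of Purkinje cells, had group log2 fold changes of -1.44 and -0.45. With 1 array left out, the weakest was -0.67 for Cbln1, without knockout 2, and -0.29 for Calb1, without wild type 1. In limma, 0 of the 15 members passed or had an unadjusted p below 0.05. The camera adjusted p was 0.125 without knockout 2 and 0.373 without wild type 2. In knockout 2 the striatum list was the highest of the 6 arrays at 0.52, the hippocampus and cortex list likewise at 0.29, and the hypothalamus and midbrain list the lowest at -0.69.

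**Figure D2:**
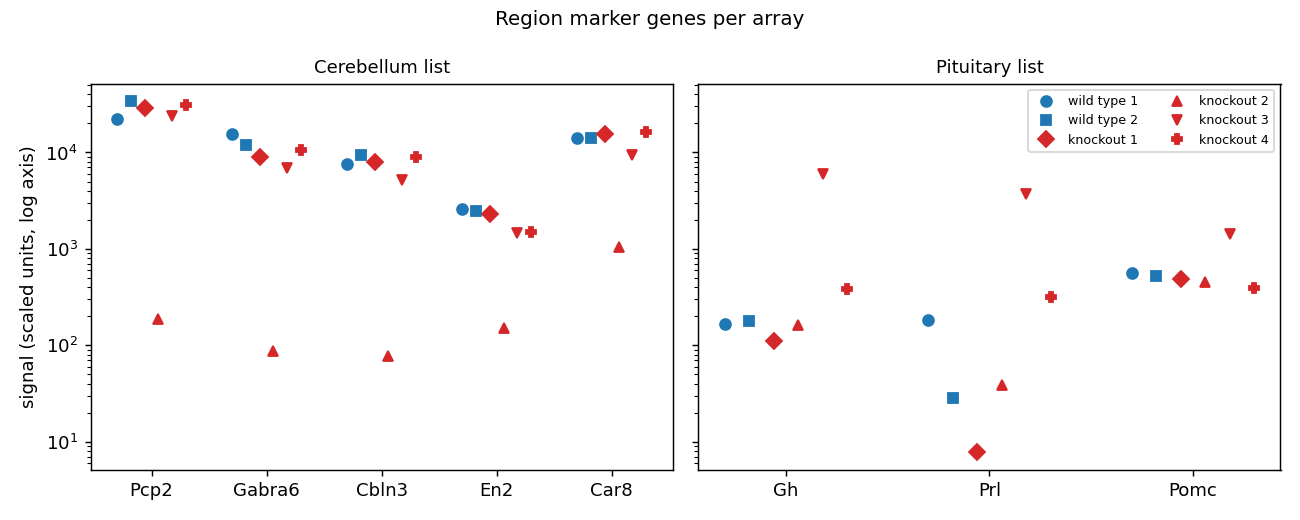
Signal in scaled units on a log axis for 5 genes of the cerebellum list and 3 of the pituitary list, 1 symbol per array, wild type in blue and knockout in red. Knockout 2 lies below the other 5 arrays for Pcp2, Gabra6, Cbln3, En2 and Car8, and knockout 3 lies above them for Gh, Prl and Pomc, with Gh at 5930 against 109.6 to 381.4.

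The other lists did not pass the camera threshold, and no member of them passed in limma when adjusted over its list alone. Oligodendrocyte markers were lower in 13 of 16 cases (camera adjusted p = 0.0606), with Ermn at -0.37. Heme and iron-sulfur genes were lower in 20 of 28 (0.0702), and striatum genes were higher in 12 of 13 (0.104). The striatum level was -0.30, 0.52, 0.25 and -0.27 in knockouts 1 to 4 and -0.050 and -0.15 in wild types 1 and 2. Without knockout 2 the striatum list had a camera adjusted p of 0.833. The camera adjusted p was 0.339 for the oxidative stress response, 0.368 for microglia and immune genes and for the pituitary, 0.441 for hippocampus and cortex, and 0.594 for other metal transport and for meninges and vascular smooth muscle. It was 0.640 for myelin lipid and cholesterol genes, 0.737 for blood, 0.767 for neurons, 0.805 for choroid plexus and ependyma and for heat shock and endoplasmic reticulum stress, 0.824 for hypothalamus and midbrain, and 0.928 for the plasminogen system. Neuron markers were even, 10 higher and 9 lower. Within these lists, the antioxidant enzymes Cat and Gpx3 had log2 fold changes of -0.48 and -0.67, and the synaptic zinc transporter Slc30a3 had 0.55, each with a limma adjusted p of 0.625. Ermn, Cat, Gpx3 and Slc30a3 here, Npas2, Ciart, Sgk1, Cdkn1a, Egr1, Egr2, Ier2 and Dusp1 above, and the cerebellum genes given per mouse were picked after their values were seen.

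No common shift was detected among the genes around Meltf, each counted by its brightest probe set. Of the 200 annotated neighbours 69 were measured, 37 higher and 32 lower in the knockout, with a median log2 fold change of 0.014 (camera p = 0.834, and p = 0.812 with an estimated correlation). Fry gave an unadjusted value of 0.0671 for change in either direction, and an adjusted p of 0.0773 over the 4 window sizes tried. Limma called 0 of them, 7 had an unadjusted p below 0.05, and the 1 below 0.01 was Bdh1, 11 genes from Meltf. That is 1.45% of the neighbours against 1.10% of the genes elsewhere (Fisher's exact test p = 0.536). Among their other probe sets, 1 of Zfp148 and 1 of Lpp also had an unadjusted p below 0.01, with log2 fold changes of 0.42 and 0.98, both picked after their values were seen.

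**Figure D3:**
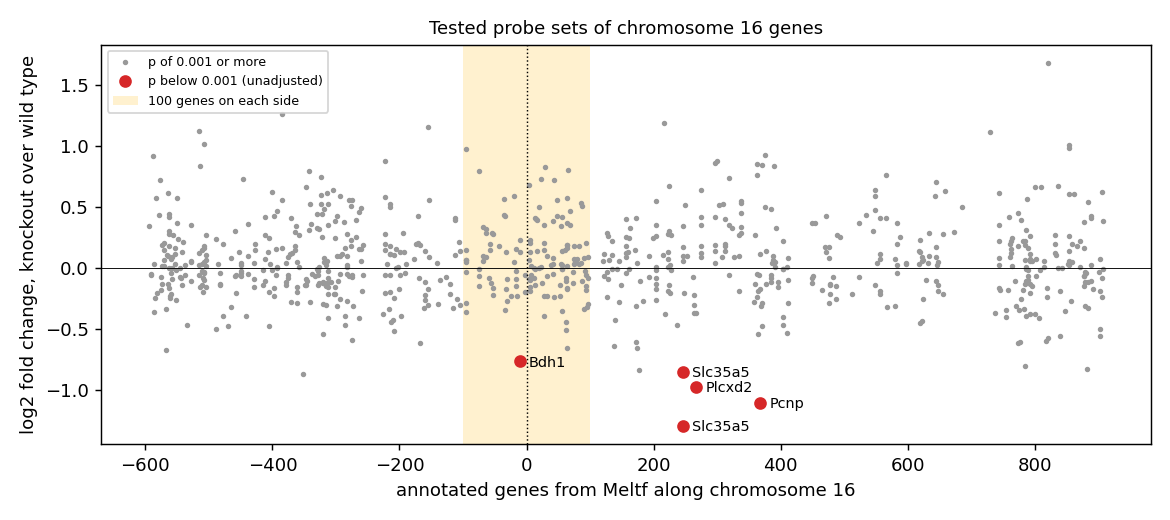
Log2 fold change, knockout over wild type, of the 816 tested probe sets of chromosome 16 genes, placed by the number of annotated genes from Meltf, with the 100 genes on each side shaded. The 5 probe sets with an unadjusted p below 0.001, in red, belong to Bdh1, Slc35a5, Plcxd2 and Pcnp and are all lower in the knockout.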

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

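The search for single arrays that stand apart was fixed as a rule in advance and ran over the 4 knockout arrays for 76 values. It picked out 1, where chance gives 3.8. Fank1, on the probe set given above, had a log2 value of 9.04 in knockout 1 and 9.27 to 9.31 in the other 3 knockouts, a gap of 0.876 of the whole range, above the 95% limit of Dixon's test for 4 samples. The wild-type arrays were not searched, so wild type 1 could not be picked out. The rule also missed the cerebellum list level of knockout 2, -2.04 against 0.062 to 0.50 in the other 3 knockouts.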

How the results depend on the processing

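The results were recomputed under the settings listed in the processing notes, and the joint removal of knockout 2 and wild type 1, the 400-gene window and the test of the share of neighbours were chosen only after the data were seen. No paired analysis was made, since each mouse was a separate animal and the labels give no pairing. Of the 592 values of the 37 named probe sets, 580 kept their direction and their side of the threshold, 8 passed it, all without wild type 2, and 4 turned direction. Both group counts and list calls rest on a few arrays, and with 1 wild-type mouse left that mouse is assumed to vary like the knockouts. Values given for lists are camera adjusted p-values. The cause of each change was not tested, except where fewer arrays or other tested probe sets make it plain. Meltf, below the dim filter, had a log2 fold change from -0.86 to -0.29.

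No probe set was called by limma in 14 of 16 alternatives. With an offset 4 times larger, 1 probe set and 1 gene passed, the dim Apod probe set, which the main filter left out. Leaving out 1 array at a time gave 0 to 414 called probe sets and 0 to 332 genes, the higher counts without wild type 2 (331 higher, 83 lower). The unadjusted p was below 0.01 for 412 probe sets, for 187 without wild type 1, for 175 without that array and knockout 2, for 1796 without wild type 2, and for 237 with the lowest 60% left out, and the share higher in the knockout was 84.5%, 86.6%, 88%, 67.1% and 76.8%. It was 78.5% after quantile normalisation and 27.7% after median centring.

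With an estimated correlation, the endothelium, cerebellum, clock and interferon lists were at 0.889 and no longer called. Fry's directional test put them at 0.823, 0.887, 0.823 and 0.823. The same test turned the iron list to higher, 0.887, and the plasminogen list, 0.970. Camera on ranks called the heme, oligodendrocyte and striatum lists at 0.0455 each and turned plasminogen, 0.997. With the mean of all probe sets of a gene, heme (0.0441), astrocyte and oligodendrocyte (0.0290 each) were called, and iron (0.923), plasminogen (0.287), neuron and heat shock (0.671 each) turned to higher.

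Quantile normalisation called oligodendrocyte (0.0401), striatum (0.0379) and immediate early genes (0.0262) and turned plasminogen (0.936). Median centring ended the calls of endothelium and cerebellum (0.0581 each) and interferon (0.0640) and turned iron (0.948). Without the dim filter, heme (0.0279) and oligodendrocyte (0.0138) were called and blood turned (0.943). With the lowest 60% left out, cerebellum (0.0619) and interferon (0.197) were lost, and choroid plexus (0.803) and hypothalamus (0.675) turned. Without the trend, iron turned (0.986).

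Without knockout 2 and wild type 1 together, microglia (0.0284) and choroid plexus (0.0218) were called lower and endothelium was lost (0.869). Interferon (0.613), iron (0.846), other metals (0.664), blood (0.426) and hypothalamus (0.533) turned to higher there, and Fth1 had a log2 fold change of -0.064. Camera's values for the neighbours of Meltf, a single set with no adjustment, turned to lower with 25 (0.415), 250 (0.463) or 400 (0.855) genes on each side, with no dim filter (0.878) and with the lowest 60% left out (0.992). Over all 24 alternatives for the neighbours the p-values ran from 0.346 to 0.992, with no call. These include fry's test of a common direction and Fisher's exact test of the share of neighbours besides camera. Fry's unadjusted values for change in either direction were 0.0144, 0.0671, 0.0773 and 0.0413 with 25, 100, 250 and 400 genes on each side, and adjusted over these 4 windows 0.0576 for 25 and 0.0773 for each of the others.

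Leaving out 1 array at a time, the called lists ranged from 0.0120 to 0.630 (endothelium, lost without knockout 2 or wild type 1), 0.00187 to 0.373 (cerebellum, lost without knockout 2 or wild type 2), 1.43e-05 to 0.414 (clock, lost without wild type 2) and 0.00622 to 0.966 (interferon, lost without knockout 1 or 2, and turned without wild type 1). Heme ranged from 0.0226 to 0.346, oligodendrocyte from 0.0129 to 0.346, striatum from 0.00239 to 0.833, immediate early genes from 0.00622 to 0.346 and choroid plexus from 0.00741 to 0.977, each called without at least 1 array, and choroid plexus turned to higher without knockout 1 (0.808), knockout 2 (0.977) or wild type 2 (0.346). Iron ranged from 0.808 to 0.990, other metals from 0.342 to 0.808, plasminogen from 0.927 to 0.984, neuron from 0.508 to 0.994, blood from 0.380 to 0.833, pituitary from 0.137 to 0.990, hippocampus and cortex from 0.151 to 0.977, hypothalamus from 0.473 to 0.966, heat shock from 0.576 to 0.965 and myelin lipid from 0.111 to 0.937, with turns of direction and no call. The log2 fold change ranged from -0.080 to 0.58 for Fth1 and from -0.26 to 0.073 for Slc11a2.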

Other observations

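The tests of the 3 patterns weighed here were chosen only after the patterns were seen, though the bounds for the cerebellum genes outside the list and for the other bright genes were set before those values were seen. Pituitary hormone genes were high in 1 mouse. In knockout 3, Gh, growth hormone, read 5930 against 109.6 to 381.4 on the other arrays, Prl, prolactin, 3690 against 7.8 to 320.5, and Pomc, the precursor of several peptide hormones, 1413 against 389.8 to 567.7. Of the 10 genes on that list 5 were above the dim filter. The choroid plexus list was highest in knockout 4 and wild type 2, at 0.33 and 0.28, and -0.23 to -0.038 on the other 4 arrays, with the folate receptor Folr1 at 1622 and 1474 against 624.9 to 1118.

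In knockout 2, transcripts of the cerebellum list were low, with Cbln3 at 77.8 against 5210 to 9323 on the other arrays and En2 at 152.9 against 1452 to 2618. A poor array is argued against, since 1 of 4545 genes with a mean of at least 2000 on the other arrays, with the listed and further cerebellum genes left out, was 4-fold or more lower there (0.022%) against 7 of the 15 on the list, and so is loss of melanotransferrin as the whole cause, since the other 3 knockouts showed 6.34% of the drop. Little cerebellum in the tissue of that mouse may account for it and stays open, as the median log2 level of 9 measured cerebellum genes outside the list was -0.90 relative to the other arrays, between the bounds of -1 set for this explanation and -0.5 set against it. Of these 9 genes 8 were at their lowest there, with Fat2, Slc1a6 and Ppp1r17 at 20, 51.5 and 62.5 against 758.2 or more, 973.6 or more and 2071 or more, and Gng13 and Rgs8 at -0.65 and -0.98 on the log2 scale. Whether the tissue was lost in dissection or the mouse itself differed was not tested.

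Transcripts with small p were mostly higher in the knockout, 348 of 412 at an unadjusted p below 0.01. Of the 15 splits of the 6 arrays into 4 and 2, too few for a share under 0.05, 3 gave as many, with 412 for the real split and 556 for the highest other, which paired knockout 1 with wild type 1. Pairs of wild type 1 with a knockout gave a median of 448, of which 67.3% to 84.0% were higher in the other 4 arrays, and pairs without it 124.5 and 38.1% to 80.7%, against 84.5% for the real split, which points to a structure of the samples centred on that array. Low signals of that array alone stay open as the source of the direction. Without it 86.6% were higher, but of only 187 probe sets, below the 270.2 that an even spread of p-values would give. The scaling between arrays stays open too, since median centring left 27.7% higher.

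The 4 genes with the smallest p among the lower ones, Pcnp, Plcxd2, Bdh1 and Slc35a5, lie on chromosome 16, which holds 431 of the 13300 tested genes, at 368, 267, 11 and 247 genes from Meltf, with Apod 15 genes away. The 15 splits are too few for a share under 0.05, and the real one gave 4 such genes among its 10 lower ones and the highest other 1, with 1 split reaching as many, the real one. A lower level of the whole transcript stays open: the ratio to the brightest probe set on the same array was -0.93 on the log2 scale (95% confidence interval -1.39 to -0.47) for Pcnp and -0.60 (-1.13 to -0.085) for Plcxd2, and for another probe set of Bdh1 and of Slc35a5 0.89 (0.37 to 1.42) and 0.94 (0.46 to 1.42), but these genes were picked for their small p, which favours such ratios, and the limma adjusted p was 0.535 for each. The remaining Slc35a5 probe sets gave -0.45 (-1.03 to 0.135), 1.02 (0.043 to 2.00) and 0.91 (0.15 to 1.66). A candidate explanation is DNA of another strain kept around the targeted gene. Apart from the 10 lower genes, 3.64% of those within 400 genes of Meltf and 2.59% elsewhere were lower at an unadjusted p below 0.05. Fisher's exact test gave p = 0.308, with an odds ratio of 1.42 and a 95% confidence interval from 0.64 to 2.78. This test cannot decide the question, since it counted only the brightest probe set of each gene. It could not see a drop confined to another probe set, such as the dim one of Apod. The explanation stays open. The labels leave it open too, as they give C57BL/6 for the wild type and C57BL/6 - Lucy for the knockout and not the strain of the targeted cells. A local effect of losing Meltf was not tested. Counted by the brightest probe set of each gene, which leaves out Pcnp and Plcxd2, the lower genes with an unadjusted p below 0.01 were Bdh1 within 25 and 100 genes and Bdh1, Slc35a5 and Poglut1, named after its values were seen, within 250 and 400, so that these counts include genes that prompted the pattern.

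Over the whole array, 9762 ratios between probe sets of the same gene gave 0 calls in limma and 843 with an unadjusted p below 0.05. Below 0.01 were 10 of 384 on chromosome 16 and 1.64% elsewhere (Fisher's exact test p = 0.153). Ratios with the smallest p were those of Prkab2, Rusc1 and Tgs1, at 1.90, 1.59 and 1.64 on the log2 scale, each with a limma adjusted p of 0.237, all 3 picked after their values were seen. The probe sets of Prkab2 and Tgs1 named above as higher in the knockout were the dimmer ones of their genes.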
